A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

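Gene expression was measured on 3 Agilent 2-colour yeast arrays of 10789 spots, of which 10263 were gene spots and 526 controls. The 6256 probes each stood for a different gene; 4007 were spotted 2 times and 2249 once. Per the labels, the RNA of the HHO1 deletion strain at 25 °C and at 37 °C was labelled with Cy3 and set against wild-type RNA from 25 °C in Cy5, and the wild type at 37 °C was labelled with Cy5 against the same reference in Cy3. Per the file headers, the 2 mutant arrays lay on 1 slide with 1 scan and the wild-type array on another, so slide, scan and dye orientation cannot be told apart from strain at 37 °C. Per the labels, total RNA was extracted with hot phenol and amplified and labelled with a linear amplification kit.

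Per the file headers, spot intensities in the deposited scanner files were made with Agilent Feature Extraction 9.1.1.1; they are mean pixel brightness per spot and channel, with the median brightness around the spot. The processed intensity in the same files had been background-subtracted with a spatial detrend and dye-normalised by that software, per the file headers. The log10 ratio of red over green in the deposited files comes from those processed signals and was read only for HHO1 and for setting the direction of the deposited value table. The authors' deposited value table holds log2 ratios, which were compared with the scanner's ratios spot by spot. The correlation was 0.951 for the deletion strain at 25 °C, 0.993 for the deletion strain at 37 °C and 0.993 for the wild type at 37 °C, which gave the direction as sample over wild-type reference. Column medians were -0.013, -0.050 and -0.020, and the slopes on the main log2 ratios were 1.14, 1.12 and 1.1. The submitters' processing notes name limma; the steps behind the table, its centring included, are not given in the sources used here.

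Intensities were processed in R 4.3.3 with limma 3.58.1. Background was corrected with normexp and an offset of 50, and log2 ratios were normalised within each array with loess, in which control spots and spots with outlier flags had weight 0. The offset draws ratios of dim spots towards 0. Flagged gene spots numbered 2, 10 and 20 on the arrays of the deletion strain at 25 °C, the deletion strain at 37 °C and the wild type, and no spot was saturated. Every ratio was turned to sample over wild type at 25 °C. A spot was used where it was well above background in at least 1 channel of each array compared, and a gene's value is the mean over its spots. The rule set before the data were examined asked for agreement between probes; with 1 probe per gene it was applied to repeat spots. Precision is limited by the number of arrays. The root mean square SD between spots of a gene was 0.065 in the wild-type heat response and 0.093 in the difference of responses. The wild-type reference channel in Cy5 differed between both mutant arrays with an SD of 0.22 over 5872 genes, and 10 genes passed the size rule; between dyes the SD was 0.23 and 2 genes passed.

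The 5 comparisons were the heat response of the wild type, the deletion at 25 °C, the heat response of the deletion strain (deletion strain at 37 °C minus 25 °C), the deletion at 37 °C (both strains over the common reference) and the difference of heat responses. No test was run, since each group had 1 array. Genes were counted past a size rule of a mean log2 ratio of 1 with each spot at 0.58 or more in that direction. For 32 gene lists fixed before the data were examined, the median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and the central 95% was taken as the range of random lists, a choice made before list values were seen. For lists of independent genes, about 8.0 of 160 list values fall outside that range by chance, and the percentile describes these arrays only. Named genes were HHO1, up to 10 highest and 10 lowest per comparison among genes past the rule and well above background in every group compared, up to 4 members per list with the largest ratios, all members of lists of up to 11 genes, and up to 4 genes per comparison with a bound. A bound sets the brighter group's signal against the higher of the lowest signal well above background in the dim channel and the gene's own, after loess and Aquantile, and is open to dye bias. Being on the scale of single channels, 28 of 94 bounds exceeded the size of the gene's ratio within arrays, and none of these is printed.

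Gene names come from the R64 assembly's gene table through the systematic name; 5756 of 6256 genes matched, 157 symbols were updated and 500 genes kept the name in the file. The genome build behind the probes is not given in the sources used here, so no coordinates are reported. Coding lengths come from the same table, where 97.1% of lengths were multiples of 3; lengths of spliced genes, many ribosomal protein genes among them, include introns.

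The calculations were tested on simulated arrays. Of 50 genes simulated at a log2 change of 1.50 in the wild-type heat response 94.0% were recovered over 5944 genes, and at 1.25 78.0%; for the deletion at 37 °C the shares were 80.0% and 68.0% over 5786 genes. No unchanged gene passed the rule in any of the 5 simulated comparisons. The changed genes were drawn from those above a signal threshold. The simulated noise was independent between genes, with no gene-specific dye or slide effect. It therefore gives no rate of false calls for the real arrays, where 10 genes passed between the reference channels of both mutant arrays. Of 200 random lists 4.0% fell outside the central range. These were random draws of simulated genes with independent noise, so the share checks only the calculation. It does not cover errors shared by the genes of a real list.

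Alternatives set before the data were examined were median centring without loess, the scanner's processed signals, no background correction, no filter on dim spots, a strict filter on both channels, channels of the same dye after loess and Aquantile (a change from ratios within arrays to channels of different arrays as well as a match of dyes), the authors' deposited table, the gene mean alone and the brightest spot. Normexp without an offset was added after the data were seen. Calculations on gene lists used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.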

Results

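Messenger RNA levels of the budding yeast Saccharomyces cerevisiae were compared between a wild-type strain and a strain lacking HHO1, the gene of the linker histone Hho1p, before and after a heat shock of 15 min at 37 °C. Cells were grown at 25 °C in rich medium to an optical density of 0.5. RNA of each sample was hybridised on a 2-colour array together with wild-type RNA from 25 °C, which served as the common reference and as the only control sample. The 3 arrays held the deletion strain at 25 °C, the deletion strain at 37 °C and the wild type at 37 °C, 1 array each. Each array carried probes for 6256 genes, and 90.0% to 90.2% of gene spots in Cy3 and 94.3% to 95.1% in Cy5 were well above background. With 1 array per group, none of the differences below has a replicate check, and the control's own spread is left out. A gene counts as risen or fallen where its mean log2 ratio was at least 1 in size and each of its spots lay at least 0.58 in that direction. The SD given after a gene is between its 2 spots on the arrays used.

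HHO1 (YPL127C) had the lowest ratio in the deletion strain. At 25 °C its log2 ratio to the wild type was -4.34 ± 0.16 (SD, 2 spots), and at 37 °C it was -3.91 ± 0.01. The HHO1 signal of the deletion strain was close to background, so the offset limits the size of these ratios, which were -5.27 and -4.79 without an offset and -6.99 and -6.77 with the scanner's processed signals. Above spot background the HHO1 signal was 13 in the deletion strain and 5473 in the wild type on the 25 °C array, and 11 against 4033 on the array of the heat-shocked deletion strain. Of the 2 HHO1 spots, 1 was well above background in each deletion channel. In the wild type the HHO1 ratio of 37 °C over 25 °C was -0.34 ± 0.02, below the size rule. Where the HHO1 probe lies relative to the deleted part is not given in the sources used here.

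The response of wild-type cells to heat was led by chaperone and stress genes on one side and ribosome assembly genes on the other. The small heat shock protein gene HSP26 rose by 7.94 on the log2 scale, 246.1-fold, the Hsp70 gene SSA4 by 7.33 and HSP12 by 6.71. The ribosome assembly gene NOG1 fell by 5.83 on the log2 scale, NIP7 was at -5.76 and the S-adenosylmethionine synthetase gene SAM1 at -5.57. Of 5974 genes, 692 rose and 978 fell.

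Among 33 measured chaperone genes 29 rose and none fell, with a median log2 ratio of 3.34, above all 10000 random lists matched on expression. HSP42 reached 6.28, HSP30 5.83 and the disaggregase gene HSP104 5.79. All 50 general stress genes rose, with a median of 3.85, led by TMA10 at 6.69, the aldehyde dehydrogenase gene ALD3 at 6.35, the polyubiquitin gene UBI4 at 5.86 and SOL4 at 5.83. Of 19 genes of trehalose and glycogen metabolism 17 rose, among them the phosphoglucomutase gene PGM2 at 5.74 and the glycogen phosphorylase gene GPH1 at 5.64. In oxidative stress defence 11 of 30 genes rose and 3 fell, and the catalase gene CTT1 reached 5.65. Of 44 genes of the citric acid cycle and respiratory chain 17 rose and none fell, with CIT1 at 2.77. Of 26 glucose-repressed genes 11 rose, led by the hexose transporter genes HXT5 at 5.33, HXT7 at 4.36 and HXT6 at 4.14; HXT6 and HXT7 are near-identical and probes cannot be assumed to tell them apart. Of 19 glycolysis genes 6 rose, and of 33 proteasome genes 1 rose, the gene of their activator Rpn4 at 1.42.

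Of 124 ribosome assembly genes 121 fell and none rose, with a median of -3.44, below all random lists. BRX1 was at -5.48, RRP12 at -5.25 and ARX1 at -5.05. Of 137 ribosomal protein genes 133 fell and 1 rose, with a median of -2.49, and RPL27B was at -4.12. All but 1 of 24 RNA polymerase I and III subunit genes fell, with RPA49 at -4.78 and RPA190 at -4.56. Translation factor genes fell in 27 of 36 cases, tRNA synthetase genes in 15 of 18 and amino acid biosynthesis genes in 20 of 45. Of 35 genes of the G1 and S phases 15 fell, led by the ribonucleotide reductase gene RNR1 at -3.44. The mating type switch gene HO was at -3.79. Of 9 core histone genes 4 fell, with HTA1 at -1.27, and the list median of -0.86 lay at percentile 10.82 of random lists, inside their central 95%. Silencing genes, with a median of -0.16, and chromatin remodelling genes, with -0.20, also stayed inside that range. GAC1, not well above background at 25 °C, was at least 10.8-fold higher after heat, and UTP13, not well above background after heat, was at least 13.0-fold lower. The share of risen genes among changed genes was 41.4%, and it was 52.5% with the scanner's processed signals, which gave 1211 risen and 1097 fallen genes and a median of 0.12 over all genes.

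The deletion strain responded to heat with the same leading groups. HSP12 rose by 7.73 on the log2 scale, HSP26 by 7.28 and TMA10 by 6.14, while SAM1 was at -5.38, the nucleolar protein gene NSR1 at -5.07 and NIP7 at -4.75. Of 5918 genes, 682 rose and 934 fell. The comparison sets the deletion strain at 37 °C against the deletion strain at 25 °C, both in Cy3 on 1 slide and each over the wild-type reference in Cy5.

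Chaperone genes rose in 30 of 33 cases with a median of 2.90, and general stress genes in 49 of 50 with 3.74. PGM2 and SOL4 each reached 5.75 and GPH1 5.45. Ribosomal protein genes fell in 136 of 137 cases with a median of -2.77, and RPS26B was at -4.18. Ribosome assembly genes fell in 122 of 124 with a median of -2.85, including NOG1 at -4.55 and NOP1 at -4.48. RNA polymerase I and III genes fell in 23 of 24 cases and had the same median as in the wild type, -2.01. Of the core histone genes HTA1 was at -1.74, HTB1 at -1.56, HTA2 at -1.54 and HTB2 at -1.13, and the list median of -0.81 lay at percentile 11.06. Of 5 measured mitochondrially encoded genes OLI1, with 1 spot, fell by 1.65. Over the wild-type reference OLI1 was at -0.59 after heat and at 1.06 at 25 °C, so the fall rests largely on the 25 °C array. In the wild type its heat response was -0.82, below the size rule. PHM7, not well above background at 25 °C, was at least 33.7-fold higher after heat. The share of risen among changed genes was 42.2%, and 31.9% with median centring in place of loess, which moved the median of all genes to -0.19.

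The heat responses of both strains were close. Over 5876 genes Pearson's r was 0.977 and Spearman's rho 0.958; these are correlations across genes, which are not independent replicates, and the 2 responses share no channel. Both strains had 593 risen genes in common, where independent lists would share 79.7, and 854 fallen genes, where they would share 155.5. No gene rose in one strain and fell in the other. The SD of log2 ratios over genes was 1.30 in the wild type and 1.24 in the deletion strain.

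**Figure D1:**
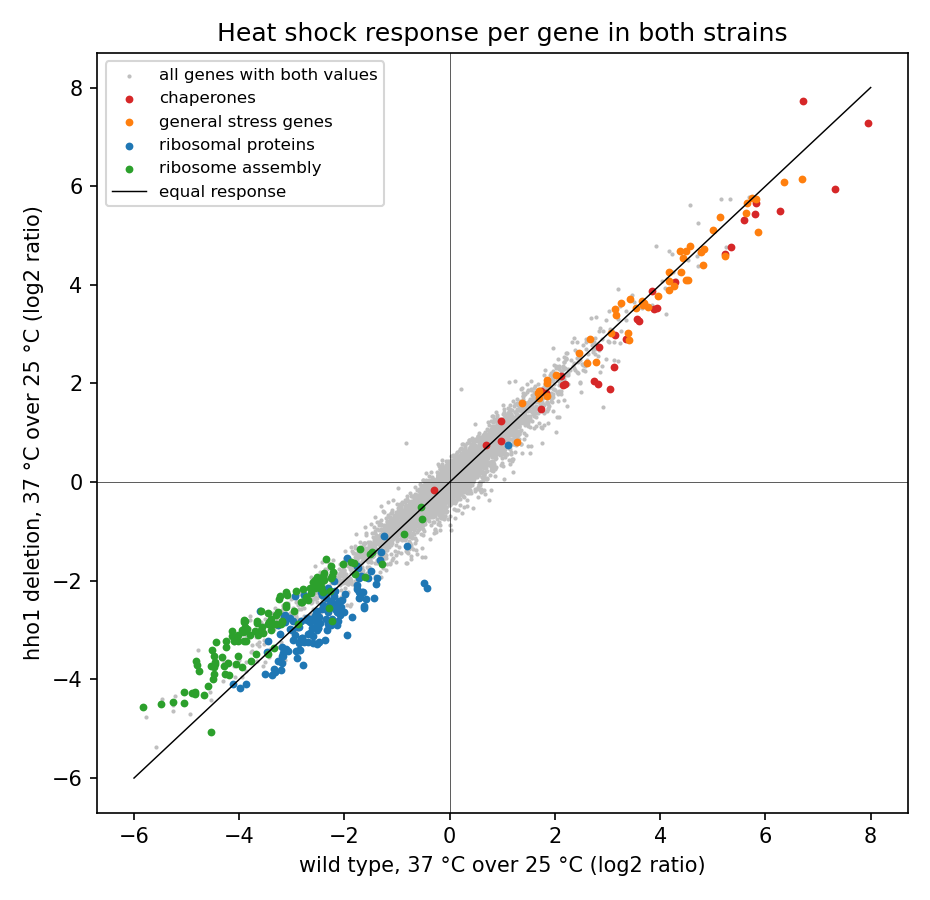
Each point is a gene, with the log2 ratio of 37 °C over 25 °C in the wild type on the horizontal axis and in the HHO1 deletion strain on the vertical axis; 4 gene lists are coloured and the line marks equal response. Points lie along the line (r = 0.977), with ribosome assembly genes mostly above it (median difference 0.56) and ribosomal protein genes mostly below it (median difference -0.34).

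At 25 °C the deletion changed few transcripts besides HHO1. Of 5984 genes 3 rose and 1, HHO1 itself, fell. The risen genes were the mitochondrially encoded ATP synthase gene OLI1 at 1.06, COS8, a member of a subtelomeric family, at 1.02 ± 0.01, and the hexose transporter gene HXT9 at 1.01 ± 0.08. For comparison, 10 genes passed the same rule when the wild-type reference channel of one mutant array was set against that of the other, a single-channel comparison with no difference in strain or temperature.

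Of 5984 genes 98.6% lay within 0.5 of 0. Except for OLI1 and COS8, no member of the fixed lists passed the rule, and list medians were small. Genes of the citric acid cycle and respiratory chain had a median of 0.17, with ATP1 at 0.58, and cell wall genes 0.13, with FKS1 at 0.40. Proteasome genes had a median of -0.19, at percentile 0.01 of random lists, with SCL1 at -0.42. Core histone genes ranged from HHF2 at -0.51 to HTB2 at 0.18, and 12 of 21 iron genes lay above 0, with FRE1 at 0.54, FIT1 at -0.70 and FIT3 at -0.81. The translation elongation factor genes TEF2 and TEF1, near-identical copies, were at -0.96 and -0.64. In the same-dye comparison the medians of the respiration and cell wall lists turned to -0.01 and -0.14, and HXT9 was at 0.90, COS8 at 0.45 and OLI1 at 0.08. Counts also depended on scaling, with 559 risen and 6 fallen genes under median centring and 25 and 76 with the scanner's processed signals. The share of risen among changed genes was 75% in the main setting, 98.9% and 24.8% in those settings, 27.3% in the deposited table and 0% in the same-dye comparison.

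At 37 °C few transcripts besides HHO1 differed between the strains past the size rule, and among the higher ones in the deletion strain were 4 of ribosome assembly. These were NOG1 at 1.28, CIC1 at 1.16 ± 0.11, the RNA helicase gene DBP3 at 1.16 ± 0.02 and NOP12 at 1.08, and the RNA polymerase I subunit gene RPA49 was at 1.17 ± 0.06. Of 5895 genes 11 rose and 24 fell relative to the wild type. The arrays compared carried opposite dyes on different slides, so a dye effect would enter this difference doubled, and slide cannot be told apart from strain.

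Of 124 ribosome assembly genes 110 had ratios above 0 and 4 passed the rule; their median was 0.46, above all random lists, but 0.02 and at percentile 66.57 with the scanner's processed signals. Of 137 ribosomal protein genes 5 fell, with a median of -0.36, and RPL41A was at -1.22 and RPL41B, a near-identical copy, at -1.14. Pheromone response genes had a median of 0.22 and genes specific to a mating type 0.29, with STE2 at 0.78, and under median centring these medians were -0.11 and -0.03 against -0.37 for all genes. The 4 genes beside HHO1 had a median of 0.57, with TBF1 at 0.68, and -0.04 in the same-dye comparison. ATG41 was at -1.33 ± 0.01 and at -1.74 in the same-dye comparison.

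Several of the genes and lists below changed sign in the same-dye comparison, and the glycolysis median shrank. That comparison sets single channels of different arrays against each other in place of ratios within an array. The AAA ATPase gene SAP1 had the highest ratio, 1.80 ± 0.04, and was at -1.63 in the same-dye comparison. Over the wild-type reference SAP1 was at 2.02 in the heat-shocked deletion strain, 0.13 in that strain at 25 °C and 0.22 in the heat-shocked wild type. Its ratio thus rests largely on 1 array, whose deletion channel the same-dye comparison sets against the reference of another array. SSA4 was at -1.38 and 0.78, HSP26 at -1.14 and 0.79, UBI4 at -1.13 and 1.19, and HSP12 at 1.04 and -1.03 in the main and same-dye values. Chaperone genes had a median of -0.33, and of 0.01 in the same-dye comparison. In the main setting 1 of them rose and 3 fell, among the fallen the mitochondrial chaperonin gene HSP10 at -1.48. Glycolysis genes had a median of -0.43, with ADH1 at -1.20 and GPM1 at -1.13, and -0.07 in the same-dye comparison, where both genes were at 0.26. That median was -1.01 in the authors' deposited table, and -0.29 with the scanner's processed signals, at percentile 2.86 and inside the range of random lists. The same-dye values gave 117 risen and 46 fallen genes, of which 9 were among the 35 of the main setting. The share of risen among changed genes was 31.4%, against 71.8% in the same-dye comparison, 7.9% with the scanner's processed signals and 49.4% with median centring.

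**Figure D2:**
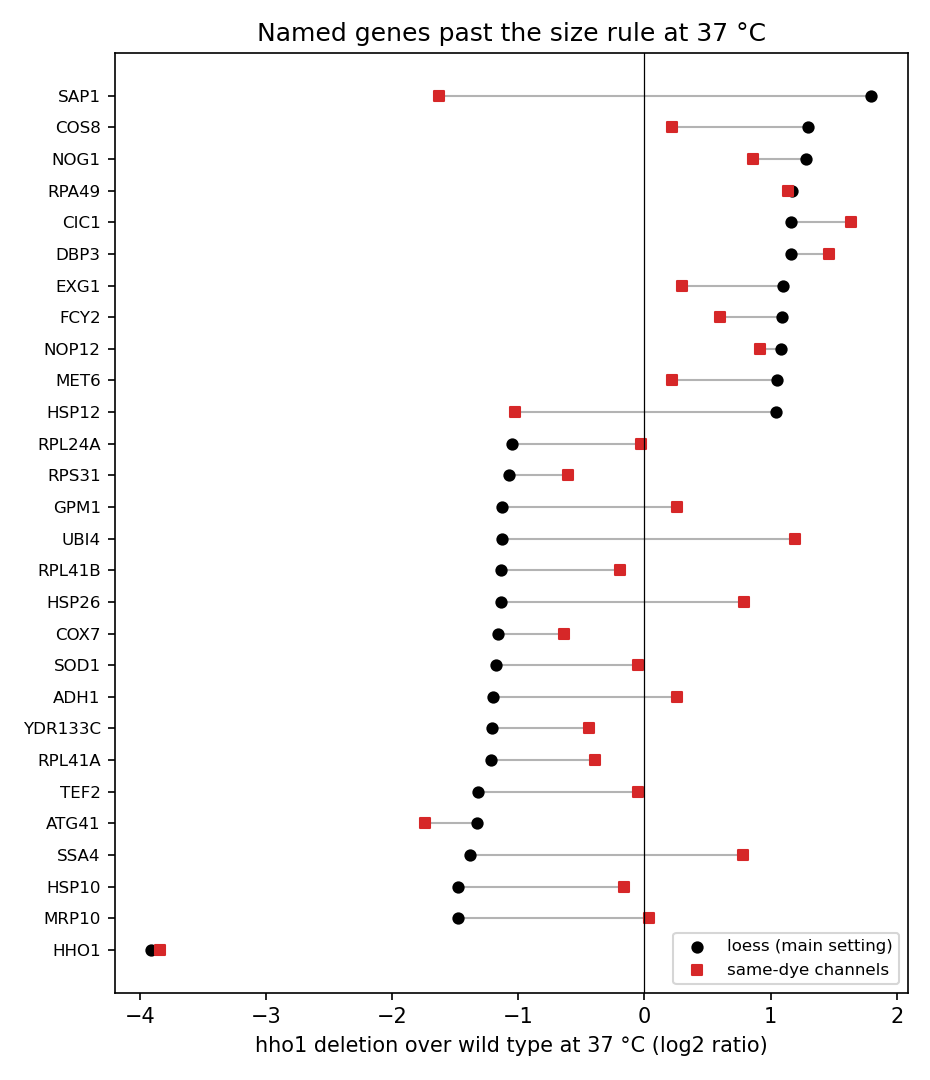
Each line shows 1 of 28 named genes past the size rule at 37 °C, with its log2 ratio of the deletion strain over the wild type on the horizontal axis, from within-array ratios (black circles) and from channels of the same dye (red squares). HHO1, RPA49, CIC1 and DBP3 keep their side, whereas SAP1 moves from 1.80 to -1.63 and UBI4 from -1.13 to 1.19.

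The difference between the heat responses of both strains was positive for most ribosome assembly genes, 114 of 124, and negative for most ribosomal protein genes, of which 27 of 137 lay above 0. The difference, deletion strain minus wild type, was 1.39 ± 0.06 for RPA49, 1.27 for NOG1, 1.21 for YTM1 and 1.19 for NOP12, and -1.71 ± 0.07 for RPL41A and -1.55 ± 0.01 for RPL41B. Values of single genes were not adjusted for coding length, with which the difference correlated. The shortest of 10 length classes had a median difference of -0.21. Of 5872 genes 22 had a higher and 9 a lower response past the size rule. Of these, 18 and 9 were well above background in every group compared.

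Of 124 ribosome assembly genes 11 passed the rule, all upward, among them CIC1 at 1.13, RPF2 at 1.13, UTP9 at 1.12 and ALB1 at 1.12. The list median was 0.56, above all random lists, and it stayed above 0 in every alternative run, from 0.13 with the scanner's processed signals to 0.75 in the same-dye comparison. It also shrank in the authors' deposited table, where the brighter and dimmer members had medians of 0.18 and 0.23. RNA polymerase I and III genes had a median of 0.20, and -0.13 with the scanner's signals and -0.04 in the authors' deposited table. Ribosomal protein genes had a median of -0.34 with 3 passing the rule downward, and -0.06 in the same-dye comparison. Among these was RPL14B at -1.14. Pheromone response genes had a median of 0.23, with FAR1 at 0.85 and STE4 at 0.73. G2 and M phase genes had 0.25, which was -0.20 under median centring, where the median of all genes was -0.34. The mating type switch gene HO was at 1.07 ± 0.08, having fallen by 3.79 in the wild type and by 2.72 in the deletion strain. ATG41 was at -1.38, and core histone genes had a median of -0.27 with none past the rule. SAP1, at 1.67 and COS12, at 1.62, were at -1.57 and -0.53 in the same-dye comparison, and SSA4, at -1.39, was at 1.88. The share of higher among changed genes was 71.0%, against 83.9% in the same-dye comparison, 15.6% with median centring, 7.9% with the scanner's processed signals and 8.7% in the deposited table.

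**Figure D3:**
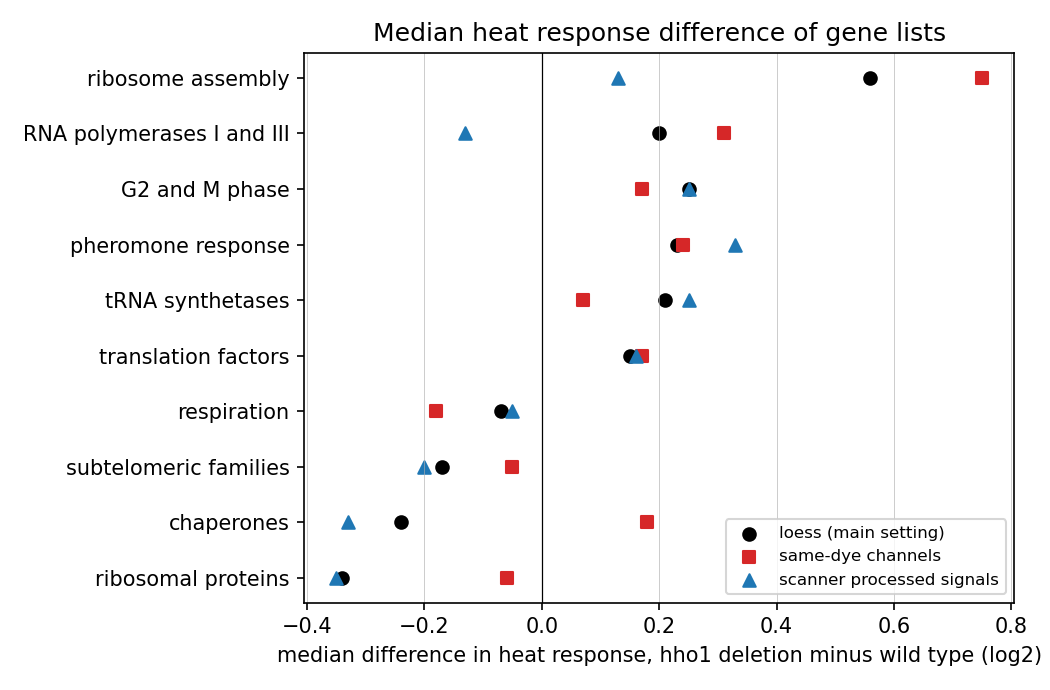
Median over the members of 10 gene lists of the heat response difference (deletion strain minus wild type, log2), in the main setting (circles), from channels of the same dye (squares) and from the scanner's processed signals (triangles). Ribosome assembly genes lie above 0 in the 3 settings drawn, at 0.56, 0.75 and 0.13, whereas chaperone genes move from -0.24 to 0.18 when channels of the same dye are compared and RNA polymerase I and III genes from 0.20 to -0.13 with the scanner's signals.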

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

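The setting of normexp without an offset was chosen after seeing the data; the other alternatives were set before. No paired analysis was possible because each group had 1 array and no test was run. Of the gene and list values recomputed under alternatives, 6029 kept their call and direction or, for genes below the size rule, moved by no more than the spread between spots (0.1 for single spots). A further 1689 moved by more than that or, for lists, left the range of called medians, 114 gene values no longer passed the size rule, and 50 called values changed sign. Of 76 list medians outside the range of random lists, 74 stayed outside it on the same side without background correction, without a filter on dim spots, with the strict filter, with the brightest spot and without an offset, 70 with median centring, 68 in the deposited table, 66 with the scanner's processed signals and 54 in the same-dye comparison. In the same-dye comparison 2 took the opposite side, ribosome assembly at 25 °C (percentile 100) and chaperones for the response difference (98.34), and with the scanner's signals 1 did, RNA polymerase I and III for the response difference (1.63). The strict filter left 687 of 724 gene values. The correlation of both heat responses ranged from 0.941 with median centring to 0.978, and 23 genes were called in opposite directions with the scanner's signals and 1 in the deposited table. Signal over background limits genes that fell with heat, since Cy3 spot background was 212 on the array of the heat-shocked deletion strain and Cy5 background 91 on that of the wild type. The cause of the changes below was not tested.

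Counts of genes moved as follows. With median centring, 559 were higher and 6 lower for the deletion at 25 °C, 590 and 605 at 37 °C, and 50 and 270 for the response difference. With the scanner's processed signals, 1211 rose in the wild-type heat response, 25 were higher and 76 lower for the deletion at 25 °C, 29 and 340 at 37 °C, and 257 lower for the response difference. Without background correction, 1 was higher at 25 °C and 20 higher and 12 lower at 37 °C. In the same-dye comparison, 0 were higher and 17 lower at 25 °C, 117 and 46 at 37 °C, and 52 higher for the response difference. In the deposited table, 6 were higher and 16 lower at 25 °C, 28 and 100 at 37 °C, and 6 and 63 for the response difference. With the brightest spot 17 were higher at 37 °C. Without an offset, 5 were higher and 7 lower at 25 °C, 63 and 81 at 37 °C, and 61 and 31 for the response difference. At 37 °C the share of higher among changed genes was 62.5% without background correction, 42.5% with the brightest spot and 43.8% without an offset, and for the response difference 81.8% without background correction.

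In the same-dye comparison these medians changed sign for the deletion at 25 °C: ribosome assembly 0.21, oxidative stress defence -0.14, respiration -0.01, glucose-repressed genes -0.05, ergosterol -0.14, cell wall -0.14 and subtelomeric families -0.08. At 37 °C they did for chaperones 0.01, tRNA synthetases -0.23, phosphate -0.04, cell wall -0.11 and neighbours of HHO1 -0.04, and for the response difference for chaperones 0.18. Genes that changed sign were at 37 °C HSP26 0.79, MRP10 0.04, SAP1 -1.63, SSA4 0.78, HSP12 -1.03, GPM1 0.26, UBI4 1.19 and ADH1 0.26. For the response difference they were SAP1 -1.57, SSA4 1.88, HSP12 -0.55, COS12 -0.53, YLR460C 0.38 and PHM7 -0.16.

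Median centring moved the median of all genes to -0.37 at 37 °C, -0.34 for the response difference and -0.19 for the heat response of the deletion strain, so sign changes there are partly shifts of 0, and no list was called in the opposite direction. Among the lists below, phosphate and G2 and M phase at 37 °C and phosphate and cell wall for the response difference left the upper range of random lists, at percentiles 95.4, 93.63, 90.4 and 84.03; the others stayed above it. With median centring, medians changed sign at 25 °C for oxidative stress defence -0.02, ergosterol -0.07 and subtelomeric families -0.01, and in the heat response of the deletion strain for meiosis -0.12. At 37 °C they did for tRNA synthetases -0.65, phosphate -0.55, cell wall -0.55, G2 and M phase -0.36, mating type -0.03 and pheromone response -0.11. For the response difference they did for tRNA synthetases -0.40, translation factors -0.49, phosphate -0.45, cell wall -0.50 and G2 and M phase -0.20, and HSP12 was at -0.73 and PHM7 at -0.60. With the scanner's processed signals, RNA polymerase I and III genes changed sign for the response difference at -0.13, and HSP12 at -0.28 and, at 37 °C, at -0.12. In the deposited table RNA polymerase I and III genes at -0.04, cell wall genes at -0.02 and HSP12 at -0.07 changed sign for the response difference.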

Other observations

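Among the tests below, those on ratio compression, on glycolysis genes at 25 °C and on coding length among genes selected by the deletion strain's heat response or by the mean of both responses, the setting of normexp without an offset and the requirement that members lie well above the offset were chosen only after results had been seen. The test on the signal floor was set after the list's median under other background treatments was known.

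Phosphate starvation genes moved apart within their list under heat. In the wild type PHM7 rose by 4.57 on the log2 scale, while the acid phosphatase genes PHO12 and PHO11, near-identical copies, were at -3.56 and -3.44 and the phosphate transporter gene PHO89 at -3.42; of 19 members 3 rose and 10 fell. Cell wall genes split in the same way, with 9 risen and 6 fallen of 36, PIR3 at 2.53 and SCW10 at -4.00. Of 24 ergosterol genes 14 fell in the wild type and 10 in the deletion strain, with ERG3 at -2.63 and -2.71. Of 24 pheromone response genes 10 fell in the wild type, where FAR1 was at -2.56, and 7 in the deletion strain, where it was at -1.71. The DNA photolyase gene PHR1 rose by 2.36 in the wild type and 2.92 in the deletion strain. Genes on the list of subtelomeric families, whose members were picked by name pattern, had a median of 0.36 in the wild type, with COS3 at 0.91.

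Ribosome assembly genes fell less in the deletion strain than in the wild type, by a median of 0.56. A single compression factor fitted to them would put the medians of ribosomal protein and general stress genes at 0.40 and -0.62, where they were -0.34 and -0.05. That argues against 1 factor shared by all genes as the whole cause, but not against compression confined to dim signals. Ribosomal protein genes were brighter, with median signals above spot background of 3916 and 841 in the heat-shocked deletion strain for brighter and dimmer members. In the direction of compression moved RNA polymerase I and III genes (0.20), tRNA synthetases (0.21), translation factors (0.15) and chaperones (-0.24). In the same-dye comparison ribosomal protein genes were at -0.06, where the factor would give 0.47. The list stayed above all random lists (percentile 100) in that comparison, which still holds the heat-shocked strains in different dyes, and with lists matched on expression and coding length (percentile 100), which argues against gene-specific dye bias and length as the whole cause. A background floor of the mutant channel stays open: the 62 brighter members also lay at percentile 100, but that preset bound was wrong, because after heat even these had a median signal above spot background of 80 in the deletion strain, close to the offset of 50, and 157 in the wild type. Dimmer members had a higher median than brighter ones without an offset (0.85 against 0.51) and in the same-dye comparison (0.82 against 0.60), which goes with a floor. Both parts were close in the main setting (0.58 against 0.55) and with the scanner's processed signals (0.13 against 0.14). In the deposited table both were smaller than in the main setting (0.23 against 0.18). The median was 0.60 without background correction, 0.62 without the offset and 0.13 with the scanner's processed signals, where background and dye normalisation change together; which step shrinks it was not isolated, and an effect of the deletion remains a hypothesis that cannot be told apart from slide.

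Ratios between the strains correlated with coding length: Spearman's rho across 5555 genes, which are not independent replicates, was 0.219 for the deletion at 25 °C, 0.36 at 37 °C and 0.25 for the heat response difference, but -0.03 and 0.038 for the heat responses of the wild type and the deletion strain; the shortest of 10 length classes had a median response difference of -0.21. That class was at -0.19 for the deletion at 37 °C but at 0.0 at 25 °C. A constant dye effect would enter the 25 °C ratio and the response difference alike. From class 4 on, class medians of the response difference lay between 0.05 and 0.11 without a further rise. In the same-dye comparison, which also replaces ratios within arrays by channels of different arrays, rho for the response difference was 0.089, a value that goes with a dye effect without isolating it. Among 2598 genes within 0.5 of 0 in the wild-type heat response rho was 0.245, which is consistent with labelling or recovery that depends on transcript length. Which strain's response carried the trend depended on the selection: rho was -0.035 in the wild type and 0.128 in the deletion strain for genes selected in this way, and -0.163 and 0.008 for genes within 0.5 of 0 in the deletion strain. For genes within 0.5 of 0 in the mean of both responses, rho was -0.123 in the wild type and 0.07 in the deletion strain. For the response difference of those genes it was 0.253. Both technical explanations stay open, and no biological explanation was tested.

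Glycolysis genes had a median of -0.43 in the deletion strain at 37 °C (-1.01 in the deposited table, and -0.29 at percentile 2.86 with the scanner's processed signals). Against random lists of each member's 40 nearest genes in expression the median lay at percentile 1.36, so genes of similar brightness did not share the shift in full. Those lists left out the members themselves, so a bias of the very brightest spots stays open. In the same-dye comparison, which also sets channels of different arrays against each other, it lay at percentile 76.6 with a median of -0.07, so a dye effect may account for part of the pattern. A constant dye effect of that size would give -0.21 at 25 °C, where the list median was 0.04 (percentile 72.64, and 89.27 among nearest genes), but members went both ways (SD 0.34). Member by member, the 25 °C values minus those such an effect would give had a median of 0.04 and an SD of 0.2, so a dye effect stays open for the members that fell, and dye and deletion are not separated.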
